A study of Homo sapiens with 4 samples.

How the data were processed

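The series profiled NB4 cells, a human acute promyelocytic leukemia line that carries the fusion of the PML and RARA genes, by CUT&Tag, in which an antibody tethers a transposase to chromatin and the tagged fragments are sequenced. It holds 4 libraries: 1 with an antibody against PPARα, the fatty acid-sensing nuclear receptor, 1 with an antibody against PML/RARA, and an IgG library named for each of them. The epitope of the PML/RARA antibody is not given in the sources used here, so unfused PML or RARA protein was not separated from the fusion. The measurements used here are 2 peak lists, 1 per antibody. No IgG coverage, read counts or library sizes were used here, so the sequencing depth behind each list is unknown, and so is how far depth sets the number of peaks.

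Coordinates are on hg38, per the submitters' processing notes. The same notes name Bowtie2 2.2.9, SAMtools, MACS 1.4.2 and bedtools without giving their roles, settings or order. The files have the narrowPeak layout of later MACS releases, so the caller's version is not settled. For each peak the deposited lists give a position, a summit, a fold enrichment, which is a linear ratio over background, and a q-value on the −log10 scale. The smallest −log10 q was 1.32 in the PPARα list and 1.30 in the PML/RARA list, near the −log10 of 0.05. The shortest peak was 301 bases in the PPARα list and 103 bases in the PML/RARA list, so the calls may have been made with different fragment or merging settings. Whether the IgG libraries served as controls, whether duplicates were removed and whether any region was masked is not given in the sources used here. Fold and q are the authors' values and serve only to describe, rank and filter peaks within a list. The folds of the 2 lists are not on a common scale.

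Peaks on chromosomes 1 to 22 and X were analysed, which left out 10 PPARα and 33 PML/RARA peaks. Genes came from a RefSeq table of GRCh38.p14, the same assembly as hg38, with 59792 annotated genes, of which 19974 protein-coding genes on those chromosomes were tested. The table gives each gene's start and end but neither strand nor exons. The plan, fixed before the data were examined, was written for transcription start sites. In its place each protein-coding gene was given both annotated ends, so that a peak near an end lies at either the start or the finish of the gene. For the same reason exons, introns and untranslated regions were not separated, and no genome sequence was used here, so the planned motif searches and the planned matching on GC content were not run. A gene carried a peak when a peak overlapped the window of 1 kb around either end. A summit within 1 kb of an end was counted as near a gene end, and the remaining summits were sorted into bodies of protein-coding genes, other annotated genes, and sequence between genes.

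A PPARα peak overlapped PML/RARA when it shared at least 1 base with a PML/RARA peak. The count was compared with 1000 random placements of the PPARα peaks on their own chromosomes, with widths kept and stretches over 1 Mb without any gene or peak left out, in a one-sided permutation test. A second set of placements kept each peak within the near or far class it came from. Shares carry 95% Clopper-Pearson intervals, which cover counting error over peaks only. Gene-level overlap and gene lists were tested with Fisher's exact test, two-sided for the lists, with Benjamini-Hochberg adjustment over 36 tests (12 lists by peaks of PPARα, of PML/RARA, and of both). Comparisons of PPARα among genes with a PML/RARA peak were adjusted over 12 tests, 1 per list, so their adjusted p-values are not on the same footing. Odds ratios carry 95% intervals. The difference in median fold between peaks with and without the other antibody's peak was tested by permutation with 100000 resamples, two-sided. Each antibody has 1 list and there is no replicate, so every p-value describes these lists over peaks or genes and none measures variation between libraries. Neighbouring genes can share a peak, so genes are not independent either.

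The genes named were set by a rule fixed before the data were examined: the 10 genes per list whose end peak had the highest −log10 q, the 10 genes with the best joint rank in both lists, up to 6 members of each gene list, the 5 highest-scoring peaks of each list away from gene ends, and 34 genes of interest. Where several peaks lay at a gene's ends, the one with the highest −log10 q is given. Some genes that this rule selects are not reported here, though they stay in the counts. Alternatives were stricter lists (−log10 q of at least 5, or fold of at least 5), a PML/RARA list shortened to the number of PPARα peaks, other overlap rules, and gene-end windows of 500 and 5000 bases. Random gene lists matched on gene length (10000 draws) and Mantel-Haenszel odds ratios over gene-length bins stood in for the GC matching.

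The procedures were tested on simulated data first. For the peak overlap with 9819 peaks, randomly placed lists were called in 2.5% of 40 simulations, and 19.7% of peaks were recovered as excess overlap where 20% had been planted. For the gene lists at gene ends over 19974 genes, lists of 40 genes were called in 3% of 400 simulations with an odds ratio of 1 and in 98.8% with an odds ratio of 4, at an unadjusted threshold of 0.05. For the strength of shared peaks, with 1000 simulated peaks and 40 simulations each, 2.5% were called without a shift and 100% with a shift of 1.2 times. The simulations used uniformly placed peaks, independent genes, and fewer placements and resamples than the tests on the data. They do not cover peaks that cluster or genes that share a peak. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.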

Results

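CUT&Tag peaks were mapped in NB4 promyelocytic leukemia cells with antibodies labelled PPARα and PML/RARA, with 1 peak list per antibody and no replicate. The PPARα list held 9829 peaks with a median width of 503 bases, covering 5.56 Mb. The PML/RARA list held 46021 peaks with a median width of 241 bases, covering 14.6 Mb. The authors' median fold enrichment was 6.25 for PPARα and 7.41 for PML/RARA, and the median −log10 q was 6.33 and 11.9. Read depth is unknown, and the lists differ in length, so a gene without a peak is one where no peak was called in that list.

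The series title frames the work as a cooperation between PPARα and PML/RARA, and the first comparison asks how far their peaks coincide. Of the 9819 PPARα peaks analysed, 8845 overlapped a PML/RARA peak (90.1%, 95% interval 89.5 to 90.7). Random placement on the same chromosomes gave a mean of 172 overlaps (SD 12.7 over 1000 placements, highest 215), so the observed count was 51.3-fold higher (one-sided permutation p = 0.001, the smallest that 1000 placements can give). When each placed peak was kept near to or far from gene ends, as observed, the excess was 9.30-fold (permutation p = 0.001, again the smallest possible). In the other direction, 9839 of 45988 PML/RARA peaks (21.4%, 21.0 to 21.8) overlapped a PPARα peak, which left 36149 PML/RARA peaks and 974 PPARα peaks alone. The overlap depended on the rule: summits lay within 200 bases of each other for 55.6% of PPARα peaks. With the PML/RARA list shortened to the 9819 highest-scoring peaks the share was 54.8%, still 105-fold over random placement.

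PPARα peaks lay mostly at gene ends, and PML/RARA peaks mostly elsewhere. Of PPARα summits, 53.2% (52.2 to 54.2) were within 1 kb of an end of a protein-coding gene, 24.9% were inside protein-coding genes, 6.92% were inside other annotated genes and 15.0% lay between genes. For PML/RARA the shares were 27.0% (26.6 to 27.4), 42.1%, 8.31% and 22.6%. Windows of 1 kb around gene ends made up 2.54% of the sequence available for placement. The odds ratio for a gene-end location, PPARα over PML/RARA, was 3.08 (2.94 to 3.22), with a one-sided log10 p of -528 in Fisher's exact test. This difference nearly vanished for lists of equal length. There 51.6% of the 9819 highest-scoring PML/RARA peaks lay near gene ends, and the odds ratio was 1.07 (1.01 to 1.13, Fisher's exact p = 0.0231). Peaks shared by the lists were left in for both comparisons. The lists are therefore not independent sets, and these intervals and p-values only describe them.

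The location went with the overlap. PPARα peaks that overlapped PML/RARA were near gene ends in 57.8% of cases, and the 974 PPARα peaks alone in 11.6% (9.66 to 13.8). PML/RARA peaks that overlapped PPARα were near gene ends in 57.3% of cases, and those alone in 18.7%.

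**Figure D1:**
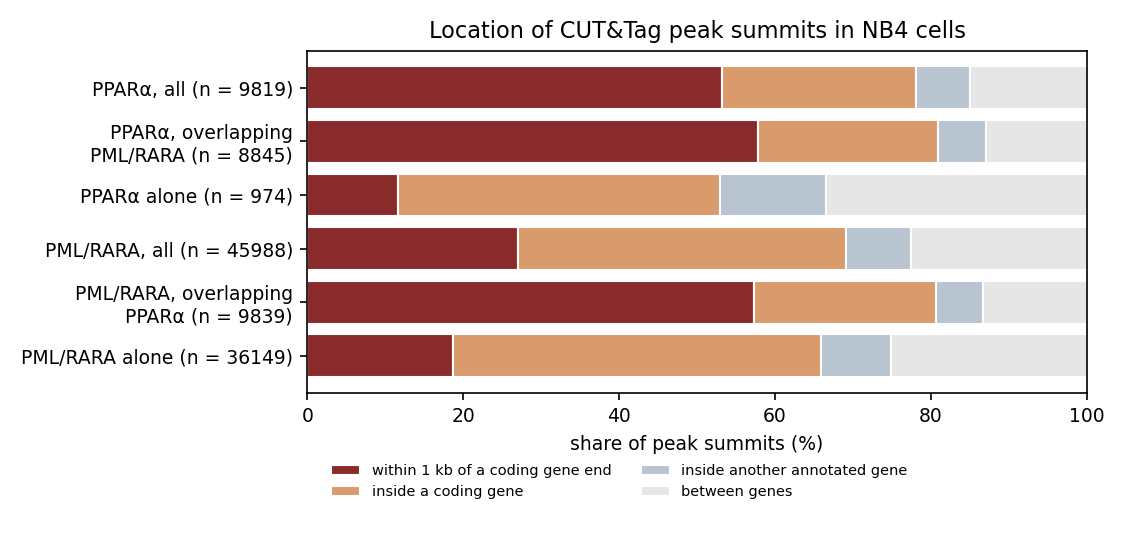
Share of peak summits, in percent, within 1 kb of an end of a protein-coding gene, inside such a gene, inside another annotated gene, or between genes, for each peak list and for its peaks with and without an overlap with the other list (n, number of peaks). The gene-end share is 57.8% for PPARα peaks that overlap PML/RARA and 11.6% for those that do not.

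Shared peaks were the stronger ones in both lists. The median fold of PPARα peaks was 6.53 with a PML/RARA overlap and 4.29 without (permutation p = 1e-05, the smallest that 100000 resamples can give). The median fold of PML/RARA peaks was 14.6 with a PPARα overlap and 6.43 without (permutation p = 1e-05, also the smallest possible). The share of PML/RARA peaks with PPARα rose with PML/RARA fold, from 11.2% in the lowest decile to 75.7% in the highest near gene ends, and from 2.73% to 47.2% away from them. At matched fold decile the odds of a PPARα overlap were 3.75 times higher near gene ends than away from them (Mantel-Haenszel, 3.56 to 3.96).

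**Figure D2:**
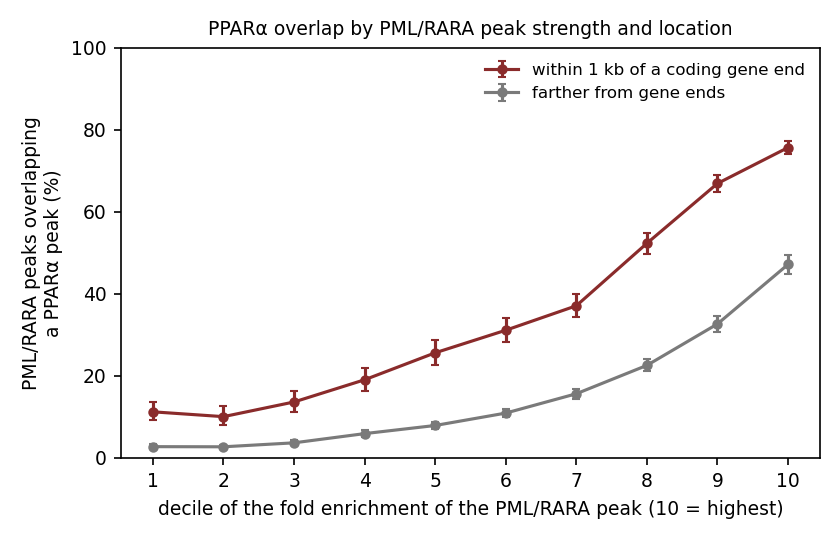
Percentage of PML/RARA peaks that overlap a PPARα peak, by decile of the authors' fold enrichment of the PML/RARA peak (10 is the highest), for summits within 1 kb of a protein-coding gene end and for all others. Bars are 95% Clopper-Pearson intervals, and the share climbs to 75.7% near gene ends and to 47.2% away from them.

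Nearly every gene with a PPARα peak at an end also had a PML/RARA peak there. PPARα peaks marked 6448 of 19974 protein-coding genes (32.3%) and PML/RARA peaks 11553 (57.8%). Both were present at 6372 genes (98.8% of those with PPARα), where independent lists would share 3730, and 76 genes had PPARα peaks only against 5181 with PML/RARA peaks only. The odds ratio was 134 (107 to 169, with a one-sided log10 p of -1818 in Fisher's exact test). It was 16.8 (15.6 to 18.1) with the PML/RARA list shortened to equal length, which moved the number of shared genes to 4453.

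The highest-scoring PPARα gene-end peak lay at MZF1, a zinc finger transcription factor gene, at chromosome 19 from 58572837 to 58573660, with a fold of 16.6 and a −log10 q of 141. A PML/RARA peak of fold 11.3 covered it. Next came KAT6B, which encodes a histone acetyltransferase (PPARα fold 16.2). Its PPARα peak reached into the gene from 74825767 to 74826926 on chromosome 10, and a PML/RARA peak of fold 17.1 (74825962 to 74827122) overlapped it but began beyond the 1 kb window, so the gene was not counted as marked by PML/RARA. RBM15, an RNA-binding protein gene, shared its peak of fold 16.1 with the neighbouring LOC124904276. MRPL4 (18.9), a mitochondrial ribosome subunit gene, NDUFA11 (15.3), a respiratory complex I subunit gene that shared its peak with VMAC, DNM2 (15.7), which encodes dynamin 2, CHD1 (18.3), a chromatin remodeller gene, and SDR42E2 (15.7) completed the group. At each of these 10 genes the PPARα peak overlapped a PML/RARA peak.

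The highest-scoring PML/RARA gene-end peak lay at NAPA, which encodes a vesicle fusion adaptor, at chromosome 19 from 47514999 to 47515616, with a fold of 31.9 and a −log10 q of 1010. DRC10 and TPCN1 shared the next (fold 30.9), at chromosome 12 from 113220973 to 113221726. CATSPERZ and ESRRA, the gene of estrogen-related receptor alpha, shared a peak of fold 18.2. TBL2 (23.3), LAPTM5 (25.5), a lysosomal membrane protein gene of blood cells, SKIL (19.0), a SMAD corepressor gene, FBXL12 (22.2) and TMEM143 (24.6) followed. Each of these 10 genes carried a PPARα peak as well, with PPARα folds from 5.04 at SKIL to 13.7 at NAPA. The best joint ranks included CCDC9, HTT, TIMM44, SF1, FBRS, DBP with its neighbour CA11, SPAG4 and CYTH2. At HTT, the huntingtin gene, the PPARα peak had a fold of 15.3 and the PML/RARA peak a fold of 20.9.

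Genes of fatty acid catabolism, many of them textbook PPARα targets, did not stand apart from other genes. PPARα peaks marked 22 of 50 (44.0% against 32.3% of other genes, odds ratio 1.66, 0.953 to 2.88, Fisher's exact adjusted p = 0.148), and PML/RARA peaks marked 32 of 50 (adjusted p = 0.479, Fisher's exact test). Both antibodies had peaks at UCP2, a mitochondrial carrier gene (PPARα fold 12.98), ETFDH (10.4), ECI2 (8.02), ECI1 (5.25) and the divergent pair HADHA and HADHB (5.69), which encode the mitochondrial trifunctional protein. CPT1A, the carnitine palmitoyltransferase of liver mitochondria, had a PML/RARA peak at an end (5.12) and a PPARα peak only inside the gene (6.32). No peak of either list lay at the ends of or inside PLIN2, PDK4 or CD36, and ANGPTL4 had only PML/RARA peaks, inside the gene.

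Triglyceride and lipoprotein genes, the subject of the series title, carried PPARα peaks at 10 of 49 (20.4%, odds ratio 0.557, 0.282 to 1.10, Fisher's exact adjusted p = 0.148) and PML/RARA peaks at 27 of 49 (odds ratio 0.891, Fisher's exact adjusted p = 0.818). Among PPARα peaks of fold 5 or more the list fell below other genes (odds ratio 0.397, Fisher's exact adjusted p = 0.0403, range over alternatives 0.0403 to 0.249). Among genes with a PML/RARA peak, PPARα marked 10 of 27 (37.0%, Fisher's exact adjusted p = 0.136), and the lower share passed with fold of at least 5 (6 of 26, odds ratio 0.316, adjusted p = 0.0267) and with windows of 5 kb (14 of 40, 0.427, adjusted p = 0.0357, range over alternatives within these genes 0.0267 to 0.506). With windows of 5 kb the PML/RARA odds ratio over all genes turned to 1.99. Shared peaks lay at AGPAT1 (PPARα fold 14.0), an acyltransferase gene of phospholipid and triglyceride synthesis, TRIB1 (9.60), GPAT4 (7.73), PLTP (7.39), SCARB1 (4.73) and AGPAT2 (4.69). LPL, the lipoprotein lipase gene, had folds of 4.13 for PPARα and 7.14 for PML/RARA, and its PPARα −log10 q was 2.60. APOA5 had a PML/RARA peak alone (6.75), and APOC3 had none.

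Sterol and fatty acid synthesis genes carried peaks of both antibodies more often than other genes. PML/RARA peaks marked 32 of 36 (88.9%, odds ratio 5.28, 1.97 to 14.1, Fisher's exact adjusted p = 0.000351). PPARα peaks marked 20 of 36 (55.6%, odds ratio 2.61, 1.365 to 4.996, Fisher's exact adjusted p = 0.0111), all of them shared with PML/RARA. Examples were LSS (PPARα fold 7.86), MVD (6.27), FDPS (5.51) and the regulators SREBF2 (6.61) and INSIG1 (5.64). The PPARα call did not pass with −log10 q of at least 5 (Fisher's exact adjusted p = 0.172) or fold of at least 5 (0.0504, range over alternatives 0.00387 to 0.172), nor among genes with a PML/RARA peak (20 of 32, odds ratio 1.33, exact adjusted p = 0.574, range over alternatives within these genes 0.258 to 1). That odds ratio fell below 1 with −log10 q of at least 5 (0.896), fold of at least 5 (0.9985) and the shortened list (0.784).

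Retinoic acid response genes carried PML/RARA peaks about as often as other genes but PPARα peaks less often. PML/RARA marked 23 of 36 (63.9%, odds ratio 1.27, 0.650 to 2.48, Fisher's exact adjusted p = 0.585), and its odds ratio fell below 1 for peaks of fold 5 or more (0.847) and for the shortened list (0.687). PPARα marked 4 of 36 (11.1%, odds ratio 0.290, 0.108 to 0.777, Fisher's exact adjusted p = 0.0145). Among these were ICAM1 (PPARα fold 6.95), RDH10 (6.87) and RETSAT (6.61). IRF1 (PML/RARA fold 18.7) and CD38 (16.0) had PML/RARA peaks but no PPARα peak at their ends, and CD38 had a PPARα peak inside the gene (5.603). The PPARα call did not pass with −log10 q of at least 5 (Fisher's exact adjusted p = 0.136), fold of at least 5 (0.0669) or windows of 5 kb (0.105). Over all alternatives the adjusted p ranged from 0.0114 to 0.136, the lower end from the random lists matched on gene length and the upper from Fisher's exact test.

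Within the 11553 genes with a PML/RARA peak, PPARα marked 4 of 23 retinoic acid response genes (17.4% against 55.2% of the others, odds ratio 0.187, Fisher's exact adjusted p = 0.00530). In the same exact test the adjusted p was 0.0457 with fold of at least 5 (odds ratio 0.309) and 0.0357 with windows of 5 kb (0.341). It did not pass with −log10 q of at least 5 (4 of 21, odds ratio 0.332, exact adjusted p = 0.0638) or with the shortened list (3 of 8, 0.226, adjusted p = 0.403).

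Myeloid and granulocyte genes did not pass the test for either antibody, with PPARα at 11 of 49 (22.4%, Fisher's exact adjusted p = 0.245) and PML/RARA at 33 of 49 (67.3%, adjusted p = 0.269). Among genes with a PML/RARA peak, PPARα marked 11 of 33 (33.3% against 55.2% of the others, odds ratio 0.415, Fisher's exact adjusted p = 0.0545), and with fold of at least 5 that difference passed, at 9 of 33 (odds ratio 0.386, exact adjusted p = 0.0267, range over alternatives within these genes 0.0267 to 0.958). Peaks of both lay at JUNB (PPARα fold 6.04), CYBA (5.51), FOS (7.17), FLT3 (5.51), RUNX1 (5.26) and GFI1 (3.91). The granulocytic regulators CEBPA (PML/RARA fold 14.8), CEBPB (9.26), CEBPE (9.50) and SPI1 (9.12), which encodes PU.1, had PML/RARA peaks at their ends without PPARα peaks there. So did TGM2 (6.08), ID2 (19.999), PRAM1 (2.98), CYP26A1 (3.95) and ANXA2 (17.1), though PRAM1 had a PPARα peak inside the gene (6.27). MYC (PPARα 7.34, PML/RARA 8.85) and MPO (3.99, 9.26), the myeloperoxidase gene, had both. PML itself had both (6.56, 13.4). RARA had no peak at its ends and 2 PPARα and 9 PML/RARA peaks inside, PPARA had a PML/RARA peak only (9.82), and RXRA likewise at its ends (7.77). In all, 9 of the 34 genes of interest had a PPARα end peak, 24 had a PML/RARA end peak, and each of the 9 was among the 24.

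Ribosomal protein genes were the most densely marked of the lists, with PML/RARA at 50 of 50 (Fisher's exact adjusted p = 4.97e-11) and PPARα at 36 of 50 (72.0%, odds ratio 5.30, 2.88 to 9.75, Fisher's exact adjusted p = 1.57e-07). Among genes with a PML/RARA peak the PPARα call did not pass (36 of 50 against 55.1% of the others, odds ratio 2.05, Fisher's exact adjusted p = 0.0630, range over alternatives within these genes 0.00185 to 0.506), except with windows of 5 kb (41 of 50, odds ratio 3.43, exact adjusted p = 0.00185). Examples were RPL4 (PPARα fold 9.74), RPLP0 (8.91) and RPL27 (7.09). Cell cycle and apoptosis genes passed for PML/RARA alone, at 23 of 28 (82.1%, odds ratio 3.12, 1.23 to 7.90, Fisher's exact adjusted p = 0.0241), and PPARα marked 12 of 28 (adjusted p = 0.297). That PML/RARA call did not pass with −log10 q of at least 5 (exact test, adjusted p = 0.0799, range over alternatives 0.0145 to 0.0799). CDKN2D, MCL1, MDM2 and DAXX carried both. Nuclear receptors and cofactors had PPARα at 13 of 36 and PML/RARA at 27 of 36 (Fisher's exact adjusted p = 0.652 and 0.0842), with both at NR1H2 and NR1H3, the liver X receptor genes, and at NR1D2 and NR2C2. Coagulation and fibrinolysis genes had PPARα at 8 of 23 and PML/RARA at 11 of 23 (Fisher's exact adjusted p = 0.825 and 0.479), among them ENO1, PLAU and F3, the tissue factor gene (PPARα fold 3.67, PML/RARA fold 22.6). The PPARα −log10 q at F3 was 1.67, close to the lowest in that list (1.32).

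Markers of other cell types carried peaks less often than other genes, though for PML/RARA the lymphoid list did not pass the main test. PPARα peaks lay at 1 of 26 lymphoid genes (CD8A), 1 of 22 erythroid and megakaryocyte genes (ANK1) and 1 of 36 liver, muscle and neuron genes (OLIG2), with Fisher's exact adjusted p = 0.00349, 0.0119 and 0.000166. PML/RARA peaks lay at 10 of 26, 4 of 22 and 8 of 36, with Fisher's exact adjusted p = 0.0926, 0.00121 and 0.000166. The PPARα −log10 q was 1.47 at CD8A, 1.32 at ANK1, which is the lowest in that list, and 3.18 at OLIG2. With windows of 5 kb the erythroid list no longer passed for PPARα (exact test, adjusted p = 0.105, range over alternatives 0.00394 to 0.105) or PML/RARA (0.249, range 0.000581 to 0.249). Among genes with a PML/RARA peak, PPARα marked 1 of 10 lymphoid genes (Fisher's exact adjusted p = 0.0417), 0 of 4 erythroid genes (0.0808) and 1 of 8 liver, muscle and neuron genes (0.0630). These calls moved with the setting. The lymphoid list did not pass with −log10 q of at least 5 (exact adjusted p = 0.0635), windows of 5 kb (0.0813) or the shortened list (0.631, range over alternatives within these genes 0.0267 to 0.631). The liver, muscle and neuron list passed with fold of at least 5 (0 of 7, exact adjusted p = 0.0267) and windows of 5 kb (4 of 17, 0.0357, range over alternatives within these genes 0.0267 to 0.913). The lymphoid list did pass for PML/RARA with both stricter lists and the shortened one (odds ratios 0.321, 0.389 and 0.135, exact adjusted p from 0.00758 to 0.376 over all alternatives).

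**Figure D3:**
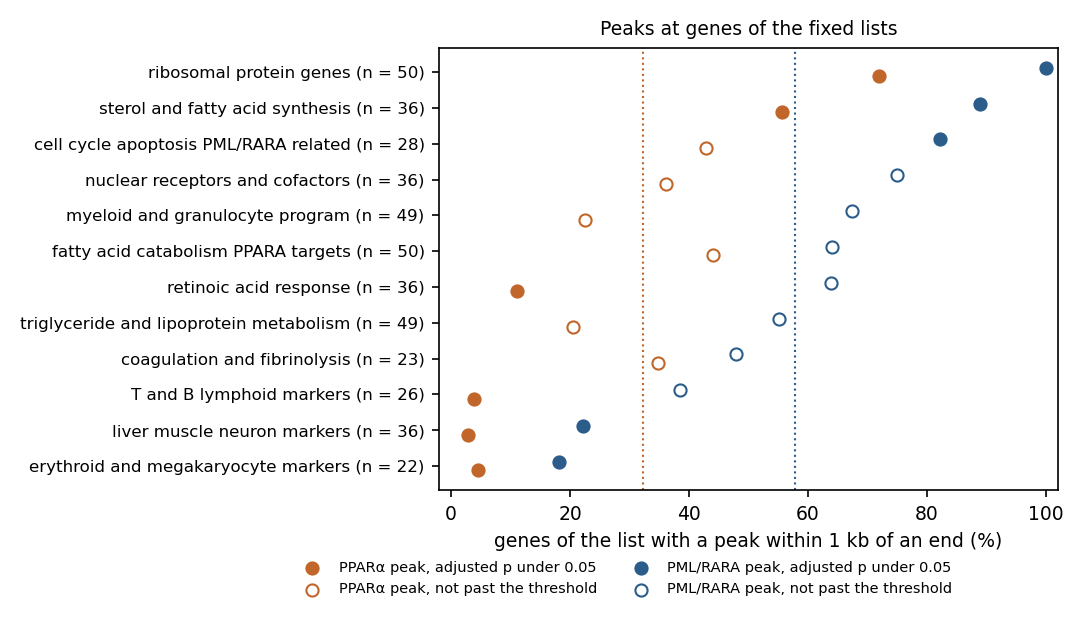
Percentage of the genes of each list (n, number of genes) with a PPARα or PML/RARA peak within 1 kb of either gene end. Filled points passed Fisher's exact test after adjustment, open points did not, and dotted lines give the share over all protein-coding genes, 32.3% for PPARα and 57.8% for PML/RARA; ribosomal protein genes lie at 72.0% and 100%.

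Away from gene ends, the highest-scoring peak of each list fell in the array of U2 small nuclear RNA genes on chromosome 17. It spanned 43251404 to 43251968 for PML/RARA (fold 70.1, −log10 q 3877) and 43251438 to 43252257 for PPARα (fold 25.2, −log10 q 222), at the snRNA gene LOC124904138. The array holds 13 annotated snRNA genes, RNU2-1 among them, with 22 PML/RARA and 9 PPARα peaks between 43231835 and 43324889. A PML/RARA peak at chromosome 7 from 73587618 to 73588238 (fold 29.7) lay 5195 bases from MLXIPL, which encodes the carbohydrate response factor ChREBP. Besides the peak at KAT6B, the other leading PPARα peaks away from ends lay on chromosome X from 115732256 to 115732861 (fold 25.03), 81722 bases from PLS3, on chromosome 18 from 107198 to 108965 (6.86), and on chromosome 3 from 75668920 to 75669621 (21.6), over the pseudogene DUX4L26. The KAT6B peak is the one named above among gene-end peaks: it overlapped the 1 kb window, but its summit lay outside. With the U2 array left out, together with peaks within 500 kb of the first or last gene of a chromosome or of a gene-free stretch over 1 Mb, 90.2% of PPARα peaks overlapped PML/RARA.

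**Figure D4:**
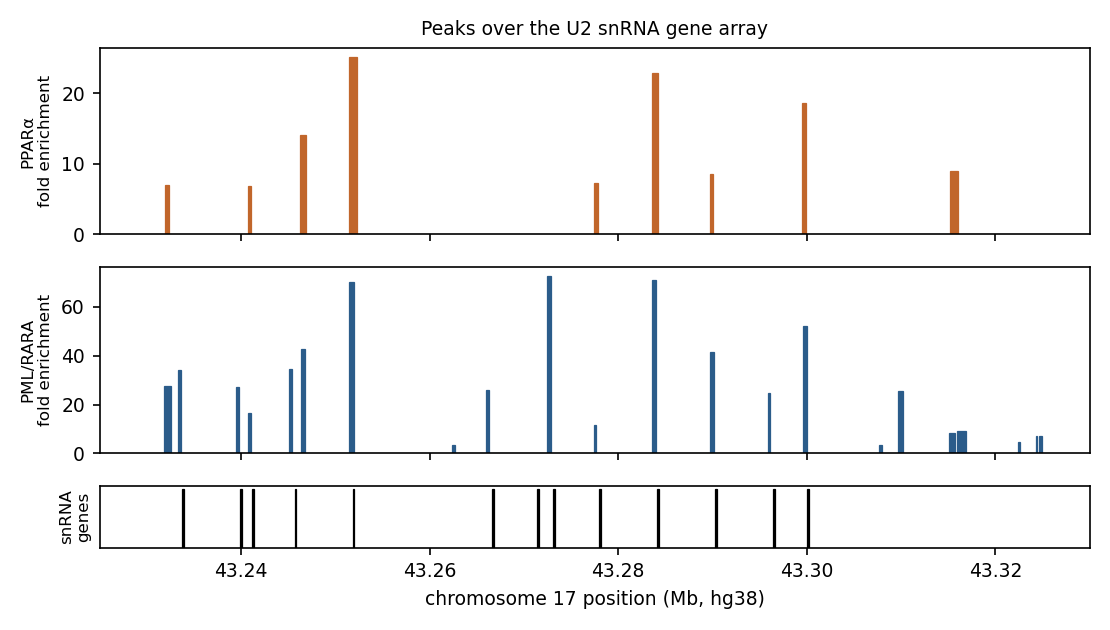
Fold enrichment of each PPARα peak and each PML/RARA peak across the U2 snRNA gene array on chromosome 17 (position in Mb, hg38), with the annotated snRNA genes in the lowest track. The highest peaks reach 25.2 for PPARα and 72.9 for PML/RARA.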

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

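The displacement by 10 to 100 kb, the gene-length matching and the comparison within PML/RARA-bound genes (alone and with each threshold) were chosen after the data had been seen. So were the strength test on the shortened PML/RARA list and the omission of the U2 array with peaks near outermost genes or gene-free stretches. All other alternatives were chosen before. Annotated repeats were not removed in any of them. Under every alternative run, the overlap stayed above random placement (9.12-fold to 105-fold), the gene-level odds ratio stayed above 1 (16.8 to 229), and shared peaks had the higher median. The PPARα preference for gene ends kept its direction (odds ratio 1.07 to 3.59), nearly ending with lists of equal length. With −log10 q of at least 5, 6040 PPARα peaks remained, 97.0% of those on chromosomes 1 to 22 and X overlapped PML/RARA, and 62.1% of PPARα and 31.3% of PML/RARA summits lay near gene ends. With fold of at least 5 these shares were 95.05%, 59.3% and 31.1%. The shortened PML/RARA list gave an overlap of 54.8% and a gene-end share of 51.6% for PML/RARA. An overlap covering 50% of the shorter peak gave 80.5%, and summits within 200 bases gave 55.6%. Gene-end shares for PPARα and PML/RARA were 62.4% and 42.9% at 5000 bases, 48.0% and 21.6% at 500 bases, and 61.1% and 34.5% with the ends of all annotated genes. Shorter windows lower the gene-end shares by construction.

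Of the gene lists, 6 passed for PPARα, and 2 passed among PML/RARA-bound genes, against 0 there with −log10 q of at least 5, 5 with fold of at least 5, 4 at 5000 bases and 0 with the shortened list, where no erythroid gene was left to test. Odds ratios changed side of 1 in 15 of 239 comparisons, and only the sterol list among these had passed the main test. They were retinoic acid response for PML/RARA at fold of at least 5 (0.847) and in the shortened list (0.687), coagulation for PPARα (0.790) and for both (0.621) at fold of at least 5, triglyceride and lipoprotein genes for PML/RARA at 5000 bases (1.99), and, among PML/RARA-bound genes, nuclear receptors (0.757) and cell cycle genes (0.884) for PPARα. Among PML/RARA-bound genes under a second change they were, for PPARα, fatty acid catabolism (0.999) and sterol genes (0.896) with −log10 q of at least 5, sterol genes (0.9985), nuclear receptors (0.9985) and coagulation (0.817) with fold of at least 5, sterol (0.784) and cell cycle genes (0.520) in the shortened list, and nuclear receptors (0.891) at 5000 bases. The cause was not tested. Of the others, 33 lost and 7 gained the threshold. Folds at named genes differed from the main value in 27 of 794 comparisons, as another peak came first in a wider or narrower window, and 74 of 90 named genes still had a PPARα end peak with −log10 q of at least 5. The planned motif searches with their alternatives, and the planned GC matching, were not run because no genome sequence was used here. Unknown depth limits every statement on absent peaks.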

Other observations

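The counts by gene class and gene family, and the tests of list length, of open promoters, of tissue-restricted genes, of all snRNA genes and of the height of the U2 peaks, were chosen after the results had been seen. Genes of tRNAs, transcribed by RNA polymerase III, carried peaks of both antibodies, also far from protein-coding genes. PPARα peaks lay at 157 of 443 tRNA genes (35.4%) and PML/RARA peaks at 236 (53.3%). Of the 333 tRNA genes over 5 kb from any protein-coding gene end, 81 (24.3%) had a PPARα peak and 148 (44.4%) a PML/RARA peak. For snoRNA genes equally far away the counts were 7 and 33 of 889, and for long non-coding RNA genes 420 and 1401 of 12708. MicroRNA genes and pseudogenes also had far lower shares than tRNA genes. The tRNA genes did not stand alone, as snRNA genes equally far away had 35 (26.1%) and 49 (36.6%) of 134. That count includes genes of the U2 array, whose peaks may hold piled reads. Outside the array, at any distance from protein-coding genes, 38 (27.0%) and 52 (36.9%) of 141 snRNA genes had a peak. Neighbouring genes can share a peak here too. RN7SK, the 7SK RNA gene, had folds of 11.9 for PPARα and 19.4 for PML/RARA. RNU7-1, the U7 RNA gene of histone mRNA processing, had 12.1 and 13.4.

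Gene families were grouped by symbol prefix, 74 families in all, and 8 differed from other genes in how often PML/RARA-bound members carried PPARα (Fisher's exact test, Benjamini-Hochberg adjusted). PPARα marked 28 of 32 PML/RARA-bound CEP centrosome genes (adjusted p = 0.00929, exact test), 22 of 25 SEC secretory pathway genes (0.0138), 42 of 53 histone genes (0.0138) and 38 of 49 EIF translation initiation genes (0.0172). It marked 1 of 13 collagen genes (0.0138), 6 of 27 GPR receptor genes (0.0138), 96 of 215 SLC solute carrier genes (0.0238) and 0 of 7 olfactory receptor genes (0.0337). All 28 mitochondrial small ribosomal subunit genes with the MRPS prefix had a PML/RARA peak, and 19 a PPARα peak. No keratin gene of 55 had a PPARα peak. Histone genes cluster and divergent pairs share peaks, so these members are not independent. Ranked by −log10 q, the 1408 highest PPARα peaks all overlapped PML/RARA, and the first that did not lay on chromosome 7 from 23595147 to 23595796 with a fold of 8.96.

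The near-complete overlap of PPARα with PML/RARA was weighed against technical sources. Placements that kept only the near or far class of each peak left a 9.30-fold excess. They spread peaks evenly within 1 kb of both ends of every protein-coding gene. A shared preference for certain genes, or for positions close to an end, was not kept and is not excluded. Counted by gene, 6372 genes had both peaks where independent lists would share 3730, a smaller excess. Random positions overlapped so long a list for 1.76% of PPARα peaks, and the observed count was 51.3-fold higher. That restates the main comparison, and random positions cannot show what a longer list of non-random sites adds. With the PML/RARA list shortened to 9819 peaks the overlap fell to 54.8% of PPARα peaks. The shared genes fell from 98.8% to 69.1% of those with PPARα, so near-completeness depended on list length. A PPARα list that is only a weaker copy of the PML/RARA signal was predicted to fall evenly near and far from gene ends at matched fold. The odds ratio was 3.75 (3.56 to 3.96), and 3.46 (3.28 to 3.65) at matched −log10 q. Deciles of either score match the signal only roughly, and peak width was not matched, so a weaker copy is not excluded. Other values go with such a copy. At equal list length the gene-end shares were 53.2% for PPARα and 51.6% for PML/RARA (odds ratio 1.07), and the PPARα share rose with PML/RARA fold. Tagging of open promoters by either antibody stays open: among PML/RARA-bound genes the odds of PPARα at ribosomal protein over fatty acid catabolism genes (36 of 50 and 22 of 32, odds ratio 1.17, 0.453 to 3.04, Fisher's exact p = 0.806) decide nothing, and no IgG or accessibility signal was used here. Binding of both proteins at the same places is also open and untested, as each antibody has 1 list.

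The low share of PPARα at PML/RARA-bound retinoic acid response genes, 4 of 23, may be a feature of tissue-restricted genes at large. Gene sets matched on the decile of PML/RARA −log10 q carried 10.02 PPARα genes on average (6 to 14), and a share of 0.0024 had as few as 4. Lower PML/RARA −log10 q, at that resolution, thus does not account for all of the difference. Fold was not matched and deciles match only roughly, so weaker PML/RARA peaks at these genes are not excluded. The narrow window does not account for the low share, as 8 of 27 at 5 kb still differed (Fisher's exact p = 0.0063, unadjusted). PML/RARA-bound lymphoid, erythroid, liver, muscle and neuron markers had PPARα in 2 of 22 (9.09%), and a difference from 4 of 23 was not detected (Fisher's exact p = 0.665), so a specific link to retinoic acid is not shown. The numbers are small: the odds ratio was 0.187 in the main test, and 0.332 with −log10 q of at least 5 and 0.226 with the shortened list, where the call did not pass, but it passed with fold of at least 5 (0.309, Fisher's exact adjusted p = 0.0457).

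The highest-scoring peak of each list lay in the U2 array, whose copies are near-identical, so reads of many copies might pile on few positions. High-scoring peaks at snRNA genes were not confined to the array. Of 141 annotated snRNA genes outside the array, 38 (27.0%) had a PPARα peak and 52 (36.9%) a PML/RARA peak. The median percentiles of −log10 q of these peaks were 80.1 and 92.1 within their lists. These percentiles are against all peaks of a list, and a comparison with peaks at other gene ends was not made. The shares with a peak were below those of protein-coding genes (32.3% and 57.8%). Among 19 of the snRNA genes outside the array, chosen by symbol (U2-2, U4 to U7, U11, U12, the ATAC forms and 7SK), 16 and 19 had a peak. This comparison cannot exclude piled reads, as genes outside the array also belong to families with several copies, such as U1 and U6. The height of the array peaks also remains open to piled reads. For PPARα the highest fold in the array was 1.82 times that at any other snRNA gene (25.2 against 13.9). For PML/RARA it was 2.02 times (72.9 against 36.1, at RNVU1-15, of the U1 family). How the authors treated reads with several matches is not given in the sources used here, and no biological explanation was tested.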
